A study of Mus musculus with 10 samples.

How the data were processed

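The series holds 10 libraries from mouse erythroid lines: 6 of 4sU-labelled RNA (3 J2E and 3 J2E-KLF3-ER) and 4 of chromatin (KLF3 immunoprecipitate and input, KLF1 immunoprecipitate and input). Per the labels' protocols, cells received 200 nM 4-hydroxytamoxifen, and RNA was labelled with 500 µM 4sU for 30 minutes, biotinylated, captured on streptavidin and sequenced on an Ion Proton. The third J2E library is labelled as ethanol-treated; it could not be left out, since the deposited values are pooled. Per the labels' protocols, chromatin was fixed with 0.4% formaldehyde after 3 hours of induction and sonicated to about 200 to 400 bp, and each library was made from 3 pooled replicates. The 3 J2E-KLF3-ER RNA libraries came from clones A, C and E. The labels do not say whether the J2E RNA libraries came from separate cultures, so the authors' p-values measure only the spread between these libraries.

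Per the submitters' processing notes, the build was mm9, and MACS 1.4.2, MACS2 and TopHat2 2.0.10 were used; their roles and settings, and the tool behind the RNA comparison, are not given in the sources used here. Per the file headers, the authors gave FPKM values (fragments scaled by transcript length and library size) as 1 pooled value per group. The authors' deposited log2 fold changes are J2E-KLF3-ER over J2E. Per the file headers, the table also holds a p-value, a q-value and a test statistic, a score of the authors' test. The deposited peak lists give an enrichment ratio per peak, by which the peaks are ranked, with a summit, an annotation class and the nearest transcription start site. No peak height was compared between lists.

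The RNA table names 23309 genes, of which 9619 have the authors' status OK, 13530 were not tested, 158 had too little data and 2 too much. The 93 blank rows were dropped. The deposited q-value equals a Benjamini-Hochberg adjustment over the 9619 tested genes within 5.26e-07. The smallest p-value was 5e-05, shared by 118 genes, so their q-values are tied at 0.00408. Genes at a q-value below 0.05 are called changed. The design fixed beforehand was for per-sample values; as the table holds none, its stated fallback, the authors' own q-value, was used, and no replicate could be left out or paired. The number of per-sample columns left unused is 0.

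Gene lists, the naming rule, the tests and most alternatives were fixed before the data were examined. The 21 lists covered the KLF and SP family, globins, heme synthesis and iron, red cell membrane, erythroid transcription factors, KLF1 targets, KLF3-repressed genes, KLF3 corepressors, G1/S, immediate early genes, interferon response, cholesterol synthesis, glycolysis, autophagy, apoptosis, histones, and markers of myeloid, megakaryocyte, mast, lymphoid and progenitor cells. Called members were compared with other tested genes by Fisher's exact test in each direction, adjusted over 40 tests. For lists with at least 5 tested members the median log2 fold change was placed among 10000 random lists matched in 10 bins of mean FPKM.

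Named genes follow a rule: 6 genes of the study's subject; the 12 rising and 12 falling called genes with the largest change at 1 FPKM or more in both groups, without unnamed models, small RNAs or joined rows; up to 4 called members per list, or the 2 highest if none was called; up to 6 called genes each way with peaks of both factors and 4 with a KLF3 peak alone; and the 5 highest peaks per list with the peaks of chosen erythroid genes. The values of 1 gene that this rule covers are not reported here. Peaks were assigned to genes as the authors did, at any distance. In the KLF1 list 13 gene entries had been turned into dates and were read back as March and Sept genes. All 3760 genes of the KLF3 list and 2773 of the KLF1 list had a row in the RNA table, and 3116 and 1839 were tested.

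Peaks overlapped when they shared at least 1 bp. Distances run from the summit to the start site. Shares carry 95% exact (Clopper-Pearson) intervals, which cover counting error only. Fisher's exact tests, odds ratios and bootstrap intervals treat genes or peaks as independent units and do not measure the spread between libraries or clones. Chance overlap came from 1000 random placements of the KLF3 peaks, and shared and unshared peaks were compared by permutation with 100000 resamples. Odds ratios over expression bins used the Mantel-Haenszel estimate. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Parts of the analysis were tested on simulated data, but not the random placements, the comparison of peak heights, the start site comparison or the Mantel-Haenszel estimate. Lists of 200 genes drawn with 4 times the weight for falling genes passed the Fisher test in 96.5% of trials, and unweighted lists in 5.0%. Planted overlaps among 2000 simulated peaks were recovered in 100% of cases. Adjustment over 9619 simulated genes recovered 100% of planted changes, with 4.31% of calls false. The chromosome difference was 0.127 after 0.12 was added to shuffled values and 0.00719 without. Of simulated lists of 20 genes shifted by 0.4 on the log2 scale 99 of 100 passed the median test, and of unshifted lists 11 of 100 fell outside the central 95%, where 5 would by chance, so the median test calls more lists than its threshold states.

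Alternatives were other thresholds, FPKM of at least 1 in both groups, no test, other overlap rules, 1000 top peaks, other distances and expression bins; those on chromosome groups, on lists without Klf3 and on distinct intervals were added after seeing the data. Motifs under the peaks were not analysed here, as no genome of the build was used.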

Results

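Newly made RNA and the binding of 2 Krüppel-like factors were profiled in mouse erythroid cell lines. J2E is an immortalised fetal liver erythroid line. J2E-KLF3-ER is the same line carrying KLF3, a transcriptional repressor of the family, fused to an estrogen receptor domain, so that 4-hydroxytamoxifen activates the fusion. RNA labelled for 30 minutes with 4-thiouridine (4sU) was sequenced from 3 J2E libraries and from 3 J2E-KLF3-ER libraries of clones A, C and E. Chromatin immunoprecipitation with an estrogen receptor antibody gave 1 KLF3 library (clone C), and immunoprecipitation with a KLF1 antibody gave 1 KLF1 library from K1-ER cells, which are Klf1-null erythroblasts carrying an inducible KLF1-ER fusion. Each had its own input library. KLF1 is the main erythroid activator of this family. All cells received tamoxifen except the third J2E library, which the labels give as vehicle-treated. The authors' RNA table holds 1 FPKM value per group, with their p-value and q-value. The depth of each library is therefore unknown here, and no error can be set beside an FPKM value. Coordinates are on mm9.

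The RNA comparison asked which genes differ in output between J2E and the J2E-KLF3-ER clones. It holds no J2E-KLF3-ER library without tamoxifen, so differences between the lines and clones are not separated from activation of the fusion. The third J2E library was vehicle-treated while all J2E-KLF3-ER libraries received tamoxifen, so effects of the drug itself are not fully separated either. Klf3 itself, on chromosome 5 at 65194761 to 65221368, went from 7.46 FPKM in J2E to 180 FPKM in J2E-KLF3-ER in the authors' deposited table, a log2 fold change of 4.59 (authors' q = 0.00408). Reads of the fusion transcript and of the resident gene cannot be separated in that row. Esr1, the estrogen receptor gene whose domain such fusions carry, went from 14.7 to 62.4 FPKM in the authors' deposited table, a log2 fold change of 2.08. Klf1, on chromosome 8 at 87425826 to 87429194, fell by 1.14 on the log2 scale, from 122 to 55.6 FPKM in the authors' deposited table (q = 0.00408). Falling genes outnumbered rising genes: of 9619 genes tested in the authors' deposited table, 183 fell and 79 rose at their q below 0.05. The median falling gene changed 1.94-fold and the median rising gene 1.83-fold. A change of at least 2-fold was reached by 83 falling and 28 rising genes.

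**Figure D1:**
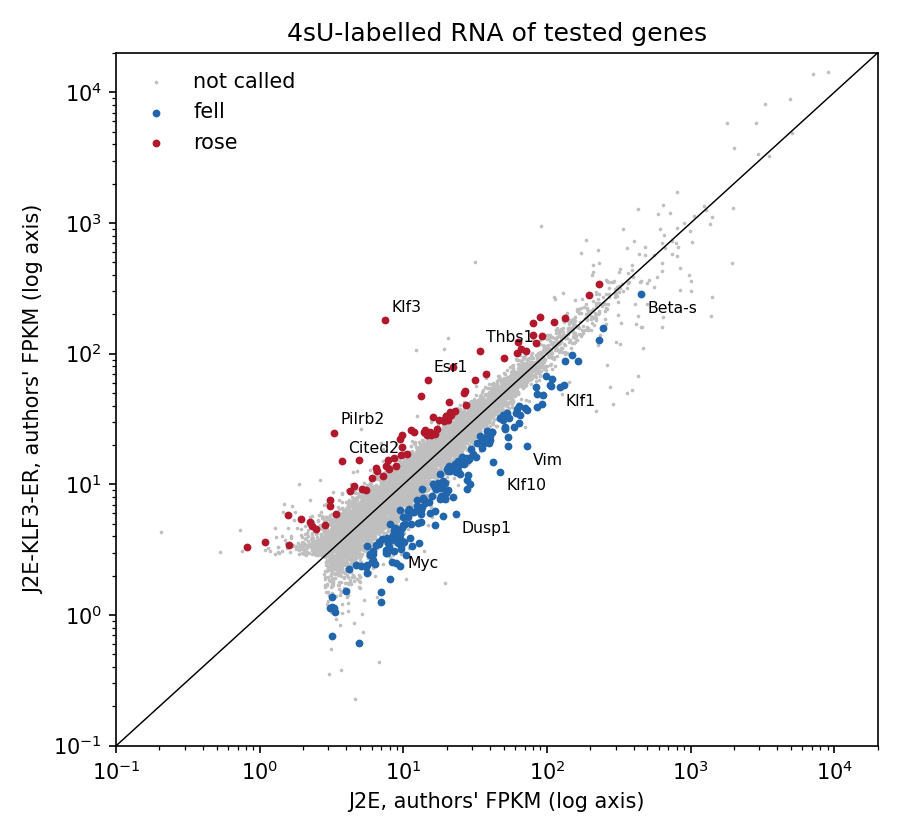
Authors' FPKM of the tested genes in J2E (horizontal log axis) and in J2E-KLF3-ER (vertical log axis), with genes that fell in blue, genes that rose in red and other tested genes in grey; the line marks equal values. Klf3 lies far above the line at 180 FPKM against 7.46, and Klf1 lies below it at 55.6 against 122.

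Among the rising genes with the largest changes were Pilrb2, a paired immunoglobulin-like receptor gene, and Cited2, a transcriptional co-regulator gene, with log2 fold changes of 2.92 and 2.02 in the authors' deposited table. Podxl, which encodes a sialomucin of the cell surface, rose by 1.72, and the receptor gene Cd200r1 rose by 1.65, both in the authors' deposited table. Thbs1, the gene of the secreted matrix protein thrombospondin 1, went from 34.1 to 105 FPKM in the authors' deposited table, a log2 fold change of 1.63. The other rising genes of this group were Syt14 (1.89), Lsm7 (1.83), Pbld1 (1.48), Psma2 (1.31) and Sh2d5 (1.30), as log2 fold changes in the authors' deposited table. The genes that fell furthest included Lrrc10, the exonuclease gene Isg20 and Sertad3, with log2 fold changes of -2.49, -2.21 and -2.08 in the authors' deposited table. Dusp1, a phosphatase gene that acts on MAP kinases, fell by 1.97, and Vim, the gene of the intermediate filament vimentin, fell by 1.89, from 72.3 to 19.5 FPKM in the authors' deposited table. Klf10 (-1.92), Dok1 (-1.88), Fut4-ps1 (-1.85), Mid1ip1 (-1.81), Agpat2 (-1.78), Nrtn (-1.77) and Spn (-1.72) complete the set, as log2 fold changes in the authors' deposited table. Every q of these genes was below 0.05, the highest being 0.0496 for Isg20 in the authors' deposited table.

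The Krüppel-like and SP family list changed in both directions. Of its 15 tested members, 5 fell, 2 rose and 8 were not called; Klf3, the transgene, is among the rising ones. Klf1, Klf10 (-1.92), Klf11 (-1.53), Klf16 (-0.92) and Sp3 (-0.71) fell and Klf6 rose (0.81), as log2 fold changes in the authors' deposited table. Falling members were enriched (odds ratio 26.5, two-sided Fisher's exact test, adjusted p = 8.09e-05 over 40 tests). The rising count gave an odds ratio of 19 (Fisher's exact test, adjusted p = 0.0400), but 9.40 with an unadjusted p of 0.109 when Klf3 was left out, a choice made after seeing the data. Adjusted over the list alone, 6 members fell and 2 rose. Klf8 was not tested by the authors. Klf6, Klf16 and Sp3 were named after their values were seen.

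Known KLF1 targets fell as a group. Of 32 tested members, 7 fell, 1 rose, which was Klf3, and 24 were not called (odds ratio 15.0 for falling, Fisher's exact test, adjusted p = 3.62e-05). The falling members included Alad, a heme synthesis enzyme gene (-1.42), the cyclin-dependent kinase inhibitor gene Cdkn1b (-1.19) and E2f2, an erythroid cell cycle regulator (-1.17), as log2 fold changes in the authors' deposited table. Adjusted over the list alone, 10 fell and 1 rose. The list median was -0.25 and lay at percentile 0.01 of 10000 random lists matched on mean expression.

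Erythroid transcription factor genes also fell: 5 of 20 tested members fell and none rose (odds ratio 17.6, Fisher's exact test, adjusted p = 0.000232). They were Klf1, Myc (-1.60), Zbtb7a (-0.94), Gfi1b (-0.78) and Gata2 (-0.55), as log2 fold changes in the authors' deposited table. Gata1 and Tal1, named after their values were seen, were not called, at -0.28 and -0.11 in the authors' deposited table. Red cell membrane genes had 3 falling and no rising members of 21 tested (odds ratio 8.72, Fisher's exact test, adjusted p = 0.0400). These were the anion exchanger gene Slc4a1 (-0.91) and the blood group genes Ermap (-0.86) and Kel (-0.66), as log2 fold changes in the authors' deposited table. Adjusted over the list alone, 6 transcription factor genes and 5 membrane genes fell. The membrane list shares members with the KLF1 targets, and the transcription factor list shares Klf1 with the KLF and SP family, so these counts are not independent.

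Of 5 tested globin rows, none was called. Hba-a2 went from 133 to 103 FPKM in the authors' deposited table (q = 0.373), and the row joining Hbb-b1 and Hbb-b2 had a log2 fold change of 0.07 in the authors' deposited table. The globin genes have near-identical copies, so their values are uncertain. Beta-s, a beta-globin row outside the list and named after its values were seen, fell by 0.67 on the log2 scale, from 453 to 284 FPKM in the authors' deposited table. In the heme synthesis and iron list, 1 of 20 tested members, Alad, fell and none rose.

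Immediate early genes fell more than other genes. Of 18 tested members, 6 fell and 1 rose (odds ratio 26.6 for falling, Fisher's exact test, adjusted p = 2.68e-05). Dusp1, Jund (-1.17) and Btg2 (-1.16), Junb (-0.95), Ier2 (-0.92) and Zfp36 (-0.79) fell and Ier5 rose by 1.21, as log2 fold changes in the authors' deposited table. Junb, Ier2, Zfp36, Egr1 and Fos were named after their values were seen; Egr1 and Fos were not called, at 0.46 and -0.17 in the authors' deposited table. Adjusted over the list alone, 7 fell and 2 rose.

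Cholesterol synthesis genes moved the other way: 4 of 20 tested members rose and none fell (odds ratio 31.7, Fisher's exact test, adjusted p = 0.000185). The rising members included Idi1, an isomerase gene of the pathway (1.05), Sc4mol (0.96) and Insig1 (0.55), as log2 fold changes in the authors' deposited table. The list median was 0.42, above all of 10000 matched random lists, and adjusted over the list alone 8 members rose.

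No enrichment passed the threshold in the other lists. Of 30 tested G1/S genes 2 fell, namely Cdkn1b and E2f2. Pklr fell by 0.78 and Gapdh rose by 0.70 among 15 glycolysis genes, and Bbc3, a pro-apoptotic BCL2 family gene, fell by 1.36 among 18 apoptosis genes, on the log2 scale in the authors' deposited table. Oasl1 fell among 6 interferon response genes, by 0.72 on the log2 scale in the authors' deposited table. Of 65 tested histone genes 2 rose and 2 fell, with Hist1h2bj at 1.10 and Hist2h3c2 at -0.96 in the authors' deposited table; histone genes also have near-identical copies. None of 12 KLF3 corepressor genes and none of 20 autophagy genes was called. Of the genes recorded as repressed by KLF3, only Fam132a was tested, at -0.35 with a q of 0.580 in the authors' deposited table, and Lgals3 was not tested. Marker genes of other blood cells gave little: none of 4 myeloid, 4 megakaryocyte and 1 progenitor genes was called, no lymphoid marker was tested, and the only mast cell marker tested was Gata2. Adjusted over the list alone, 1 G1/S gene rose and 3 fell. The progenitor list had only Hhex tested, so its p-value of 0.0297 by the authors' test stood unadjusted there and passed. Its log2 fold change was 0.37 and its q 0.251 in the authors' deposited table. The other lists of this paragraph kept the counts above.

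Fold changes also differed by chromosome, in groups chosen after seeing the data. The median log2 fold change of tested genes lay between 0.02 and 0.22 on chromosomes 1 and 10 to 19 and between -0.07 and 0.01 on chromosomes 2 to 9 and X, so that each of the 11 chromosomes of the former group stood above all 9 of the latter. The group medians were 0.11 and -0.03. In the former group 54 genes rose and 75 fell of 4680 tested; in the latter, 25 rose and 108 fell of 4938 tested (odds ratio 3.11 for rising among called genes, Fisher's exact test, p = 5.12e-05). Falling genes were thus 58.1% of calls on the former and 81.2% on the latter. The smallest change of any called gene with values above 0 in both groups was 0.49 on the log2 scale in the authors' deposited table, beyond the largest chromosome median. This does not free the calls of the offset, which can still carry a gene near the threshold across it. The 6 lists named above as enriched also stood apart from matched random lists once values were centred within each chromosome group.

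**Figure D2:**
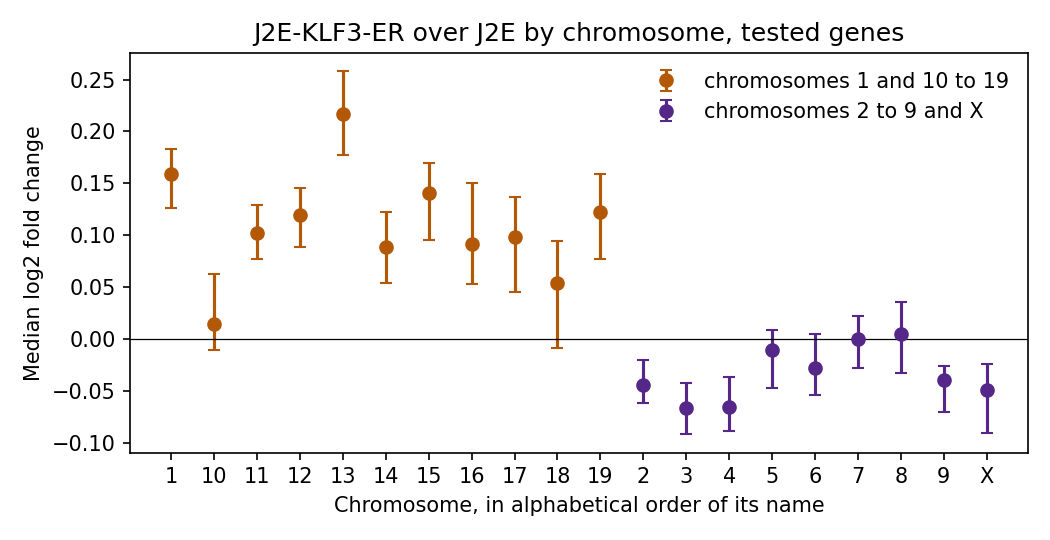
Median log2 fold change of tested genes (J2E-KLF3-ER over J2E, vertical axis) for each chromosome (horizontal axis, in alphabetical order of the names); bars are 95% bootstrap intervals over genes. Medians on chromosomes 1 and 10 to 19 (orange) reach 0.22, and those on 2 to 9 and X (purple) stay at or below 0.01.

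The binding comparison asked where KLF1 and KLF3 sit and which sites they share. The lists hold 3800 KLF1 peaks and 4579 KLF3 peaks, each list called from pooled immunoprecipitations, so no replicate test of binding could be made. Some intervals are listed more than once with different summits, and distinct intervals number 3623 for KLF1 and 4230 for KLF3. Shares and tests count each listed peak separately. KLF3 peaks lay mostly at promoters and KLF1 peaks were spread further out. The lists differ in factor, cell line and antibody at once. They may also differ in peak caller, as the roles of MACS 1.4.2 and MACS2 are not given. The tests therefore compare these lists and not the factors alone. Of the KLF3 peaks 81.2% (95% exact interval 80.1 to 82.3) had their summit within 1 kb of a transcription start site, against 41.0% (39.4 to 42.6) of the KLF1 peaks (odds ratio 6.22, two-sided Fisher's exact test, p = 8.4e-323). The median distance was 159 bp for KLF3 and 2738 bp for KLF1. In the authors' annotation, introns held 37.3% of KLF1 peaks and 18.3% of KLF3 peaks, and distal sites held 23.4% and 8.80%. The highest KLF1 peaks were at the promoters of Arrb1 (chromosome 7, 106683394 to 106683855, enrichment 80.9), Snx22 (chromosome 9, 65917390 to 65917878, 78.2) and Zfp28 (chromosome 7, 6335739 to 6336252, 74.9), followed by a distal site near 1700019O17Rik (72.4) and the promoter of the kinase gene Pim1 (69.7). The highest KLF3 peaks were all at promoters, those of Cbwd1 (chromosome 19, 25036004 to 25036454, 47.5), Ppp1r15b (44.0), Oxsr1 (42.2), Hnrpll (40.1) and Brpf1 (39.5). Enrichment values are the authors', and intervals on peak shares cover counting error only.

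Of the KLF3 peaks, 1559 of 4579 (34.0%, 95% exact interval 32.7 to 35.4) overlapped a KLF1 peak by at least 1 bp, and 1493 of 3800 KLF1 peaks (39.3%, 37.7 to 40.9) overlapped a KLF3 peak. When the KLF3 peaks were shifted at random by 10 kb to 1 Mb, a median of 12 and at most 25 overlapped in 1000 placements (permutation p = 0.001, the smallest these can give). Such shifts do not keep peaks at promoters. Among tested genes, 1035 had a KLF1 peak and 2795 a KLF3 peak within 1 kb, and 850 had both, where 301 would be shared by independent sets (odds ratio 15.7, Fisher's exact test, p = 8.43e-314). KLF1 promoter peaks overlapped a KLF3 peak in 72.9% of cases, but KLF1 intron and distal peaks in 22.9% and 21.7%. For KLF3, 30.7% of promoter peaks overlapped a KLF1 peak, against 40.6% of intron and 46.7% of distal peaks. Shared peaks were higher than unshared peaks of the same list: median enrichment was 11.6 against 9.04 for KLF1 and 9.18 against 7.59 for KLF3 (permutation test, 100000 resamples, two-sided, p = 1e-05 in both, the smallest they can give). All 5 top peaks of each list were shared.

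**Figure D3:**
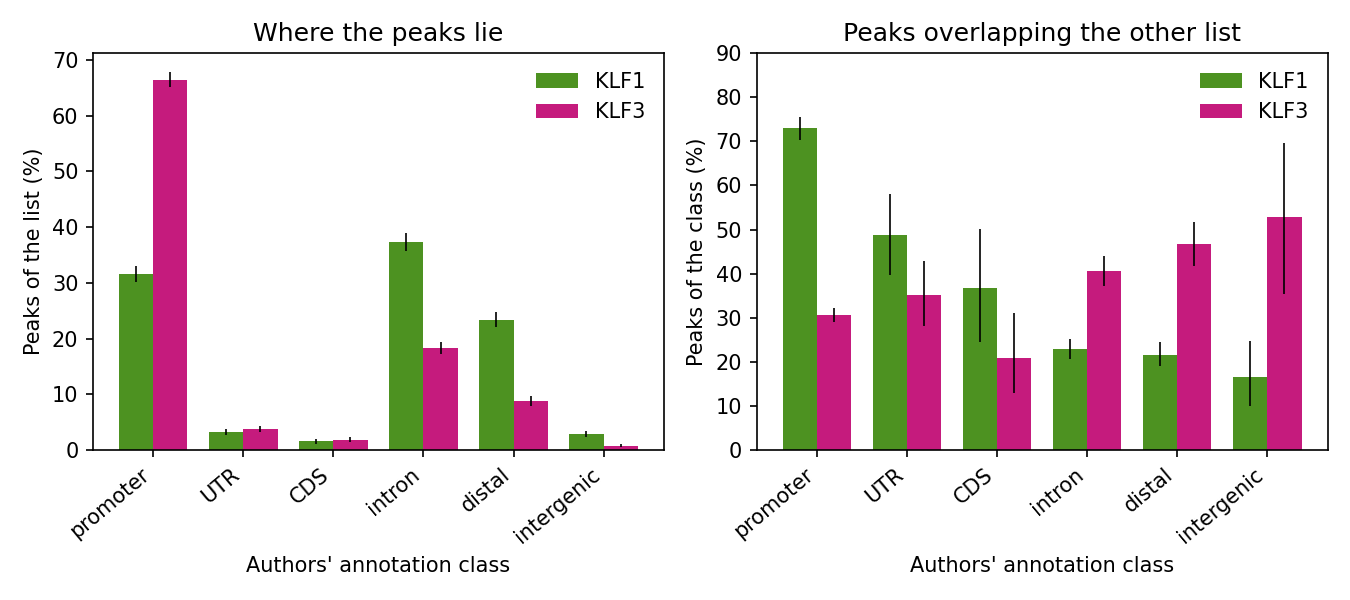
Left, share of KLF1 (green) and KLF3 (magenta) peaks in each annotation class (percent of the list); right, share of the peaks of each class that overlap a peak of the other factor (percent of the class), with 95% exact intervals as bars. Promoters hold 66.5% of KLF3 peaks and 31.6% of KLF1 peaks, and 72.9% of KLF1 promoter peaks are shared.

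At erythroid genes, the Gata1 promoter held a KLF1 peak of rank 31 (chromosome X, 7544839 to 7545325, enrichment 50.5) overlapped by a KLF3 peak (14.6). An E2f2 intron held a KLF1 peak at chromosome 4, 135733504 to 135734196 (33.8), overlapped by a KLF3 peak (13.2). The authors assigned 2 KLF1 promoter peaks to the alpha-globin gene Hba-a1, an unshared peak (32.9) and, beside the start of the Hba-a2 row at 32196488 on chromosome 11, a peak (20.6) shared with a KLF3 peak of rank 4578 (3.12). Tal1, Ank1, Slc4a1 and a site near Hbb-y had shared peaks, whereas the intron peak of Alas2 (14.7) was a KLF1 peak without KLF3. The Tfrc promoter carried a KLF3 peak (17.3) and none of KLF1. Klf3 had a KLF3 peak at its promoter (chromosome 5, 65193863 to 65194339, enrichment 6.86) and another in an intron (6.71), and no KLF1 peak. Klf8 had a KLF3 peak (9.17), Lgals3 a KLF1 promoter peak (15.4) and Fam132a 3 KLF1 peaks, the highest at 9.82. Klf1 had no KLF1 peak and 2 KLF3 peaks, both annotated as coding sequence, at chromosome 8, 87427133 to 87427548 (26.6) and 87428564 to 87428916 (14.2). No other gene had 2 or more KLF3 peaks that all lay in coding sequence. No peak was assigned to Esr1, Bcl11a or Epb4.2.

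Setting binding against RNA asked whether genes near peaks changed more often. The KLF1 peaks come from K1-ER cells, not from the lines whose RNA was compared. Genes that fell carried peaks more often than other tested genes. A KLF3 peak was assigned to 92 of 183 falling genes (50.3%) and to 32.0% of the other tested genes (odds ratio 2.14, 95% interval 1.58 to 2.91, two-sided Fisher's exact test, adjusted p = 1.12e-06 over 6 tests). A KLF1 peak was assigned to 75 falling genes (41.0% against 18.7%, odds ratio 3.02, 2.21 to 4.11, Fisher's exact test, adjusted p = 1.83e-11), and peaks of both to 61 (33.3% against 12.7%, odds ratio 3.44, 2.47 to 4.75, adjusted p = 5.23e-12). Chromosomes 2 to 9 and X held 108 of the 183 falling genes, but 66 of the 92 with a KLF3 peak. The KLF3 odds ratio there was 3.38, with a peak at 61.1% of falling genes and 31.8% of other tested genes. The other chromosomes were not run alone. By these counts, their falling genes had a KLF3 peak only slightly more often than the 32.0% of other tested genes. The KLF3 link thus came almost wholly from chromosomes 2 to 9 and X. Rising genes had a KLF3 peak less often, in 16 of 79 (20.3% against 32.5%, odds ratio 0.528, 0.284 to 0.926, Fisher's exact test, adjusted p = 0.0321). For KLF1 peaks and for peaks of both, the rising genes gave odds ratios of 0.611 and 0.544 (Fisher's exact test, adjusted p = 0.179 for each). With the 1000 top peaks the KLF3 odds ratio for rising genes turned to 1.34 (Fisher's exact test, p = 0.421). It kept its direction without passing the threshold at an adjusted p below 0.01 (0.641) and on chromosomes 2 to 9 and X alone (0.520), with fewer rising genes in both.

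**Figure D4:**
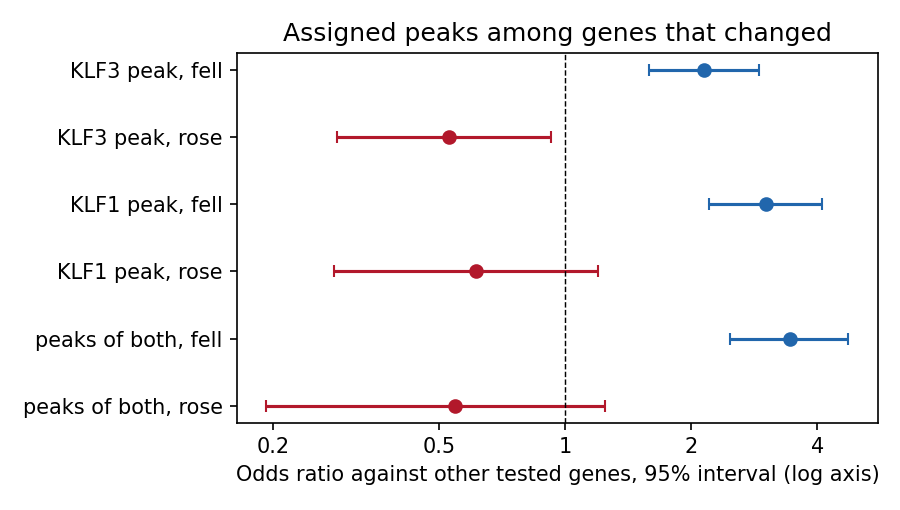
Odds ratio (horizontal log axis, 95% intervals) of having an assigned peak for genes that fell (blue) or rose (red), against other tested genes; the dashed line marks 1. The falling genes lie at 2.14 for KLF3, 3.02 for KLF1 and 3.44 for peaks of both, and the rising genes lie below 1.

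Genes with peaks of both factors had the highest share of falling genes. Of 1258 such genes 61 fell (4.85%, 95% exact interval 3.73 to 6.19), against 14 of 581 with a KLF1 peak alone (2.41%, 1.32 to 4.01), 31 of 1858 with a KLF3 peak alone (1.67%, 1.14 to 2.36) and 77 of 5922 with neither (1.30%, 1.03 to 1.62). The odds ratio of both against KLF3 alone was 3.00 (1.91 to 4.82, Fisher's exact test, adjusted p = 1.46e-06 over 7 tests), while that of KLF3 alone against neither was 1.29 (0.817 to 1.99, adjusted p = 0.298) and that of KLF1 alone against neither 1.87 (0.973 to 3.37, adjusted p = 0.0926). Both against KLF1 alone, a test chosen after seeing the data, gave 2.06 (1.13 to 4.03, Fisher's exact test, unadjusted p = 0.0154). Falling genes with both peaks included Sertad3, Klf10, Vim, Mid1ip1, Klf11 and Sertad1, the last at -1.50 in the authors' deposited table. Dusp1, Agpat2, Nrtn and Myc fell with a KLF3 peak alone. Rising genes with both peaks were Rps23 (0.99), Zfp62 (0.88), Scd1, a fatty acid desaturase gene (0.74), Gapdh (0.70), Ptma and Gas5 (both 0.53), as log2 fold changes in the authors' deposited table. Of 10 genes that rose with a KLF3 peak alone, those named by the rule were Klf3, Hibadh (1.19), Hist1h2bj and Arrb2 (1.07). These values are log2 fold changes in the authors' deposited table.

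The KLF1 list also names the nearest genes called up or down by the authors when K1 and K1-ER cells were compared. The direction of that ratio is not spelled out. Of 31 tested members of the KLF1 target list other than Klf3, 12 were named up and 0 down. Of 400 tested genes named up, 52 fell in J2E-KLF3-ER and 6 rose, with a median log2 fold change of -0.19. These made up 28.4% of falling genes and 3.69% of the other tested genes (odds ratio 10.4, 95% interval 7.23 to 14.7, Fisher's exact test, adjusted p = 3.23e-29 over 4 tests). Of 92 genes named down, 0 fell and 1 rose (Fisher's exact test, adjusted p = 0.533 for each), with a median of 0.14. Among the genes named up that fell were Klf10, the erythropoietin receptor gene Epor (-1.12), E2f2, Alad, Slc4a1, Zbtb7a and the peroxiredoxin gene Prdx2 (-0.76), as log2 fold changes in the authors' deposited table. This comparison, and the genes Epor and Prdx2, were chosen after seeing the data.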

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

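Settings on chromosome groups, distinct intervals, all KLF1 peaks for the 1000 top KLF3 peaks, lists without Klf3 and K1 labels were chosen after seeing the data. No paired analysis was possible because the deposited RNA values are pooled per group; leaving out a replicate, other pseudocounts, count tests, an estimated correlation and other splits of the libraries could not be run for the same reason. The depth of the libraries is unknown. Beside 262 called genes (79 rising, 183 falling), stricter thresholds gave 111 at 2-fold or more (28 and 83) and 145 at an adjusted p below 0.01 (34 and 111). With no test, 461 genes of the whole table were 2-fold apart on the log2(value + 1) scale, 190 higher and 271 lower. Chromosomes 2 to 9 and X alone gave 130 calls (25 rising, 105 falling) and chromosomes 1 and 10 to 19 alone 129 (54 and 75), with the p-values adjusted again over the genes of each group. With FPKM of at least 1 in both groups, 9554 of the 9619 tested genes remained and 258 were called. All 75 named genes compared kept their side of the threshold. This was nearly fixed in advance, as few genes were dropped and the p-values stayed the same. The number of enriched lists, 6, was also 6 by list medians and 6 after centring; without Klf3 the odds ratio of rising KLF1 targets was 0. By construction, the upper 0.5 of each list by enrichment held 1900 KLF1 and 2289 KLF3 peaks, and 570 and 463 reached 2 times the median. The share of KLF3 peaks overlapping KLF1 peaks, 34.0%, was 28.8% for summits within 100 bp, 30.9% within 200 bp, 32.6% over distinct intervals, 24.8% for the 1000 top peaks of both lists and 51.5% for the 1000 top KLF3 peaks against all KLF1 peaks. Start site shares and heights of shared peaks kept direction and call under every alternative run. All 24 alternatives run for falling genes kept direction and call. None was on chromosomes 1 and 10 to 19 alone, and the odds ratios ranged from 1.60 to 5.86. On chromosomes 2 to 9 and X alone they were 3.38 for KLF3, 4.85 for KLF1 and 5.01 for both, above those over all chromosomes. By the counts, the links were weaker on chromosomes 1 and 10 to 19, which were not run alone. Falling genes there had a KLF3 peak little more often than other tested genes. For rising genes with a KLF3 peak, the odds ratio by Fisher's exact test was 0.641 (p = 0.359) at an adjusted p below 0.01, 0.520 (p = 0.206) on chromosomes 2 to 9 and X, both with fewer genes, and 1.34 (p = 0.421) for the 1000 top peaks, where the cause was not tested. At 2-fold or more it passed the threshold of Fisher's exact test for KLF1 peaks (0.156, p = 0.0304) and for both (0, p = 0.0430), while both was 2.13 (p = 0.130) for the 1000 top peaks; the cause was not tested. Genes named up in K1 gave odds ratios from 10.5 to 16.5 for falling. Genes named down, with 1 rising member, gave 0 at 2-fold or more and on chromosomes 2 to 9 and X.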

Other observations

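The ribosomal protein and oxidative phosphorylation lists, the chromosome groups and the tests on K1-labelled genes below were chosen after seeing the data, as were the genes named here; of their tests, the exact test of the chromosome names and the tests on K1-labelled genes were framed only after their results were seen. Genes of the translation and respiration machinery had higher values in J2E-KLF3-ER. Of 80 tested ribosomal protein rows 7 rose and none fell, among them Rpl41, from 79.8 to 171 FPKM, Rps23, from 62.3 to 124 FPKM, and Rps14, from 80.5 to 139 FPKM in the authors' deposited table. Their median log2 fold change was 0.31 (95% bootstrap interval 0.25 to 0.37), against 0.03 over all tested genes. Eef2, a translation elongation factor gene, rose by 0.49 in the authors' deposited table. Only 15.0% of the ribosomal protein rows had an assigned KLF3 peak, against 32.4% of tested genes. The 81 tested nuclear genes of oxidative phosphorylation had a median of 0.27 (0.15 to 0.38), although none was called, and 12.3% had a KLF3 peak. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain.

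If genes named up in K1 against K1-ER are those higher with KLF1 present, a reading that rests on 12 known KLF1 targets being named up and 0 down, it is a hypothesis that they fell because KLF3 bound near them, because Klf1 itself fell, or both; with the direction turned, their fall would run against lower Klf1. Among the 400 genes, 41 of 256 with a KLF3 peak fell (16.0%) and 11 of 144 without one (7.64%), an odds ratio of 2.31 (95% interval 1.11 to 5.14, Fisher's exact test, adjusted p = 0.0196 over 2 tests). Of those falling genes, 37 of 41 and 6 of 11 also had a KLF1 peak. The odds ratio was 2.38 (0.935 to 7.18) in genes with a KLF1 peak and 1.42 (0.264 to 7.05) in genes without one. Pooled over both groups it was 2.08 (Mantel-Haenszel, 0.987 to 4.39, with p = 0.0654 by an exact test over both groups). It stayed near 2.31, but its interval includes 1, so a part for local KLF3 cannot be told apart from one for sites that also bind KLF1. Genes without a KLF3 peak still fell more often when named up than when not named, 11 of 144 against 80 of 6288 (1.27%), an odds ratio of 6.42 (3.01 to 12.5, Fisher's exact test, adjusted p = 9.86e-06). On that reading of the direction it is consistent with a part for lower Klf1, or for KLF3 sites below the authors' threshold, which were not tested.

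A candidate explanation for the ribosomal rise is carry-over of stable unlabelled mRNA into the 4sU fraction. It calls for other stable, abundant messages to rise about as much. The oxidative phosphorylation genes, the list set for that test, had a median J2E value of 16.5 FPKM, against 118 FPKM for the ribosomal protein genes. They were less abundant, so they test the explanation for stable messages only, and they did rise about as much (median 0.27). Globin rows above 1 FPKM in both groups, also of stable messages, did not, though globin genes are also KLF1 targets. Hba-a2 was at -0.37 and Beta-s at -0.67 in the authors' deposited table. Hba-x was at -0.01 and the row joining Hbb-b1 and Hbb-b2 at 0.07 in the authors' deposited table. The stability of none of these messages was measured here. A bias towards genes with short loci is argued against, because the ribosomal median lay at percentile 100 of lists matched on expression and locus length, whose own median was 0.08. Locus length includes introns, so a bias towards short transcripts was not tested and stays open. The offset between chromosome groups is argued against too, since the centred median was 0.28; altered transcription in J2E-KLF3-ER remains open.

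The split of fold changes by chromosome name was sharp: 2 of the 167960 ways to part the 20 chromosomes into groups of these sizes gave a difference as large (exact p = 1.19e-05, two-sided). The groups were chosen after these medians were seen to be fully separated, which puts the exact p-value near its minimum. It restates that separation and is no independent evidence. Expression level and locus length of the genes are argued against, as the difference of 0.14 was still 0.14 (0.142) after centring within bins of both. Processing in alphabetical chromosome order could give such a split, and so could whole-chromosome copy number, although copy number has no reason to follow names. Genes the authors did not test, 4648 at an FPKM of at least 0.1, showed a difference of only 0.04 (0.0375, exact p = 0.183), between the bounds set for processing order, so that the 2 cannot be told apart without reads per chromosome for each library. Within tested genes the difference grew from 0.09 in the lowest of 5 expression bins to 0.19 in the highest, a comparison also chosen afterwards.

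The 2 KLF3 peaks in Klf1 ranked 1 and 7 of the 86 KLF3 peaks in coding sequence, a class holding 1.88% of the list. Klf1 cDNA or plasmid DNA in the KLF3 immunoprecipitate could give peaks restricted to coding sequence. Of 666 other genes with 2 or more KLF3 peaks, 0 showed this, but chance alone would give only 0.197, so the count does not bear on it. Binding of KLF3 inside Klf1, where RNA fell by 1.14 in the authors' deposited table, stays open too, and reads across the introns would be needed to decide. No KLF3 peak in coding sequence was assigned to Klf3 or Esr1, the genes whose sequences the fusion carries.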
